A study of Mus musculus with 13 samples.

How the data were processed

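RNA was measured in mouse embryonic stem (ES) cells 3 days after withdrawal of leukaemia inhibitory factor (LIF), the cytokine that keeps such cells undifferentiated. Cells were left untreated or were given 10 µM PD169316 or 10 µM SB203580, which are pyridinyl imidazole inhibitors of the p38 mitogen-activated protein kinases. The compounds share their imidazole core and differ at the para position of the 2-phenyl ring, which carries a nitro group in PD169316 and a methylsulfinyl group in SB203580. S1 is a feeder-free ES cell line. D4 is a line that needs feeder cells and was cultured without them before the experiment. Per the labels' protocols, cells were grown with 500 pM LIF, plated at 10000 cells per ml without it, and only adherent cells were lysed, so cells that had detached were not measured.

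Per the labels' protocols, biotin-labelled cRNA was made from 5 µg of total RNA, and 10 µg of cRNA was hybridized to Affymetrix mouse arrays of 2 versions, MG-U74A (7 arrays) and MG-U74Av2 (6 arrays). The deposited values are intensities per probe set, which the authors computed with Microarray Suite 5.0 and scaled globally to a trimmed mean target intensity of 300, per the labels. The trimmed mean of every deposited array, taken without the highest and lowest 2% of its values, lay at 300.2 or 300.3. On U74A, 2611 probe sets were listed at 0 on all arrays and were not tested. The 2 tables were scaled separately, so every test stayed within a table and no level was compared across them.

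Groups came from the sample titles. On U74A there were 2 control, 2 PD169316 and 1 SB203580 array of S1 cells, and 1 control and 1 PD169316 array of D4 cells. On U74Av2 there were 2 arrays of S1 cells for each of the 3 conditions. The labels do not state that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

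Signals under 32 were set to 32 and converted to log2, which understates changes of dim genes. Probe sets with a signal of at least 100 on at least 2 arrays of a fit were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The S1 groups of a table shared one estimate of the spread, and the single SB203580 array of U74A and the single D4 arrays were assumed to vary like the others. For the combined test, the z scores of both tables were summed and divided by the square root of 2 for probe sets tested in both, and the effect size was the mean of both log2 fold changes. A gene or probe set is said to have risen or fallen where this adjusted p passed. D4 entered a fit of PD169316 with a term for the cell line, a fit of the difference between the lines, and a test of whether the PD169316 effect differed between lines, all on U74A.

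Probe sets were named from the platform annotation supplied with the data. On U74A 10276 probe sets had 1 gene symbol, 363 several and 1949 none; on U74Av2 10833 had 1, 396 several and 1193 none. No symbol could be updated, and no gene was named from a probe set with several. A gene with several probe sets was represented by the one with the highest mean signal. The named genes of an S1 comparison were the 10 largest rises and the 10 largest falls past the threshold of the combined test with the same sign in both tables; where fewer than 5 passed either way, the 5 with the smallest p were given as values. For the lines the rule took the 10 largest differences each way past the threshold, and for PD169316 in D4 the 5 largest each way as values. Up to 4 members of each list with the smallest p and 14 genes named in advance were added.

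The 26 gene lists were pluripotency; LIF and STAT3 targets; primitive and visceral endoderm; trophoblast; primitive streak, mesoderm and muscle; epiblast, ectoderm and neural; pro-apoptotic and p53; anti-apoptotic; metallothionein and oxidative stress; p38 pathway and immediate early; heat shock and chaperones; endoplasmic reticulum stress and amino acid response; cell cycle; CDK inhibitors; cholesterol and fatty acid synthesis; TGF-beta, Nodal and BMP; actin cytoskeleton and SRF targets; extracellular matrix and adhesion; fibroblast (feeder type); endothelial and blood; xenobiotic and AhR; imprinted; hypoxia and glycolysis; MYC and ribosome biogenesis; interferon and inflammation; housekeeping. Several genes sit in more than 1 list. Lists with at least 5 tested genes were tested within a table with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and limma's rotation test fry were the alternatives; no list passed either of them in any comparison.

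Groups, designs, gene lists, the naming rule and a first set of alternatives were set before the data were examined. Those alternatives were quantile normalization, no signal filter, a minimum signal of 200, floors of 1 and 100, no intensity trend, leaving out each array in turn, the replicate number as a block, and fits of only the groups compared. Further alternatives were chosen after seeing the data.

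Per the file headers, the arrays were hybridized on 5 days, coded 1 to 5 here. Day 1 held both D4 arrays, day 2 the U74A control and PD169316 arrays of replicate 2, and day 3 all S1 arrays of replicate 1 on both versions together with the U74A SB203580 array. Day 4 held the U74Av2 SB203580 array of replicate 2, and day 5 the U74Av2 control and PD169316 arrays of replicate 2. The replicate numbers thus pair control with PD169316 arrays through a shared hybridization day. Across 5369 probe sets, the deviations of same-numbered arrays from their group means correlated at r = 0.208 for control and PD169316 on U74A and 0.172 on U74Av2, 0.0839 for control and SB203580, and 0.179 for PD169316 and SB203580.

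The day 3 arrays of one treatment appear to carry the same RNA on both chip versions. Their deviations from the table means correlated across versions at r = 0.227 to 0.362 (n = 3 pairs), against at most 0.196 in any other pairing, and the log2 ratios of 20 control probe sets differed with an SD of 0.102 to 0.197, against 0.174 to 0.61 for other treatments of that day and at least 1.06 for arrays of different days. The tables are therefore not independent, although the combined test and its SEs were computed as if they were. These SEs are thus likely too small. The S1 results of PD169316 rest on 3 hybridization days. An alternative that allows for the correlation of the z scores (r = 0.429 for PD169316 against control) is printed beside the combined count of each S1 comparison. Counts per list use the combined test without it. The correlation was taken over all tested probe sets, so it may also hold effects common to both versions, and this alternative may be too strict.

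The test procedures were tested on simulated data with 100 probe sets changed at each of 2 sizes. For PD169316 over both versions, the combined test recovered 34% of changes of log2 1 and 76% of changes of log2 2 among 5204 probe sets, with 5 unchanged probe sets among 115 calls. On U74Av2 alone it recovered 1% and 35% among 6945 probe sets, and on U74A alone it made 0 calls among 5629. With day 3 deviations shared between versions, 24.1% of the calls were unchanged probe sets over 20 repeats, against 6.73% with independent deviations. A list moved by log2 1 in the U74Av2 design was recovered. Its adjusted p was 2.24e-31 by camera at the preset correlation, 0.0281 with an estimated correlation and 0.0049 with fry. The simulated genes varied independently of each other. This run therefore does not show how these tests behave on lists whose genes vary together.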

Results

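The 13 arrays measured RNA of mouse ES cells 3 days after LIF withdrawal, without or with 10 µM PD169316 or SB203580. The S1 line was measured on MG-U74A (control n = 2, PD169316 n = 2, SB203580 n = 1) and on MG-U74Av2 (n = 2 each), and the D4 line on MG-U74A (control n = 1, PD169316 n = 1). Median signals lay between 89.4 and 134 per array, and 21.8% to 29.9% of the probe sets with a value lay at or under the floor of 32. The number of arrays limits the precision. The median 95% confidence interval of a log2 fold change reached 0.82 either way for U74Av2, 1.1 for PD169316 against control on U74A, and 1.35 for SB203580 on U74A. The ratio of the 3' to the 5' probe set of Actb was 3.31 and 3.21 on the S1 control arrays of hybridization day 3, and 1.46 to 2.25 on the others. For Gapdh this ratio was highest, at 1.71, on the U74Av2 SB203580 array of replicate 2, and 0.874 to 1.58 on the others.

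The comparison of PD169316 with control in S1 asked which genes the compound alters while ES cells leave self-renewal. Rises were seen in genes of the actin cytoskeleton list, annexin genes among them (Acta1 by 2.86 ± 0.41 on the log2 scale, SE, n = 2 against 2 on each chip version), while a probe set of Actb fell. The metal-binding metallothioneins rose (Mt1 by 2.92 ± 0.25), as did keratin and basement membrane genes of the endoderm list (Krt8, 1.95). Gata4 and Gata6 of that list were not called. SEs over both versions take them as independent and are likely too small. Falls were seen in genes of Nodal signalling (Lefty1, -1.99 ± 0.36), in Pim1 (-1.09) and Mycn, and in glycolytic genes (Pfkl, -1.78). Pim1 and Mycn belong to the LIF and STAT3 list, whose members went both ways. Over both chip versions, 101 of 5369 probe sets passed the combined test (91 genes), 74 higher and 27 lower. Of these, 97 moved in the same direction in all 4 S1 pairs of same-numbered arrays. Those pairs are the arrays that gave the calls, and the day 3 pairs of both versions appear to share their RNA. Pair counts here and below are therefore no separate check. An unadjusted p under 0.05 was met by 625 probe sets, where 268 would be met by chance.

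The count of 101 treats the chip versions as independent, although the replicate 1 arrays of both appear to carry the same RNA. Allowing for the correlation of the z scores left 12 probe sets, all higher: Acta1, Anxa3, Mt2, Actn1, S100a6, Id2, Tagln, Mt1, Tmsb4x, Wfdc2, Lgals1 and 1 without a gene name. That correlation may also hold effects common to both versions, in which case 12 is too few. A limma test of 1 log2 ratio for each of the 3 hybridization days called 0. In that test 267 probe sets had an unadjusted p under 0.05, where 268 would be met by chance. With the replicate number as a block and the U74A SB203580 array left out, 199 probe sets passed, among them all 101 (104 passed without that array and without the block). Leaving out single arrays moved the count to 164 without control replicate 2 and 31 without PD169316 replicate 1 of U74A. On U74Av2 it became 48 without control replicate 1, 64 without control replicate 2, 24 without PD169316 replicate 1 and 159 without PD169316 replicate 2. Without the day 3 controls, 30 passed.

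S100a6, which encodes a calcium-binding protein, rose most, by 3.67 ± 0.33 on the log2 scale (SE; adjusted p = 2.17e-06), and was higher in 4 of 4 pairs. Its U74Av2 signal was 1310 ± 1028 with PD169316 and 122 ± 18.7 in control (SD, n = 2). Mt1 rose by 2.92 ± 0.25 (adjusted p = 1.63e-06; signal 12050 ± 71.4 against 1303 ± 704) and Mt2 by 2.35 ± 0.21 (adjusted p = 2.17e-06; 25590 ± 5023 against 4704 ± 1881), each in 4 of 4 pairs. Lgals1, the gene of galectin-1, rose by 2.87 ± 0.31 (adjusted p = 1.46e-05; 3896 ± 3008 against 454 ± 18.6). The other rises among the 10 largest were Stra8 (3.63), Anxa1 (2.91), Acta1 (2.86), Anxa3 (2.83), Tagln (2.66) and Krt19 (2.35), with adjusted p from 1.46e-05 to 0.0346 and each higher in 4 of 4 pairs.

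The kinase gene Pim2 showed the largest fall, with a log2 fold change of -2.78 ± 0.44 (adjusted p = 0.00202; U74Av2 signal 837 ± 887 against 3166 ± 640). Its ratios were -4.39 and -4.11 in the day 3 pairs, whose controls had the highest Actb 3' to 5' ratios (3.31 and 3.21), and -1.72 and -0.89 in the others. Lefty1, an inhibitor of Nodal, changed by -1.99 ± 0.36 (adjusted p = 0.00232; 381 ± 105 against 1103 ± 96.4), the Nodal co-receptor gene Tdgf1 by -1.91 ± 0.45 (adjusted p = 0.0123), and Nodal by -1.05 ± 0.24 (adjusted p = 0.0222). Each was lower in 4 of 4 pairs. The remaining largest falls were Fgf15 (-2.46), Lef1 (-1.87), Smoc1 (-1.87), Krt86 (-1.78), Pfkl (-1.78), Ldha (-1.57) and Utp14a (-1.52), with adjusted p from 0.00229 to 0.0229, each in 4 of 4 pairs. However, Lef1 was only at -0.04 in the day 2 pair and Utp14a at -0.17 in the day 5 pair. No fall passed when the correlation of the z scores was allowed for; Lefty1, Pim2 and Lef1 then had an adjusted p of 0.0524.

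**Figure D1:**
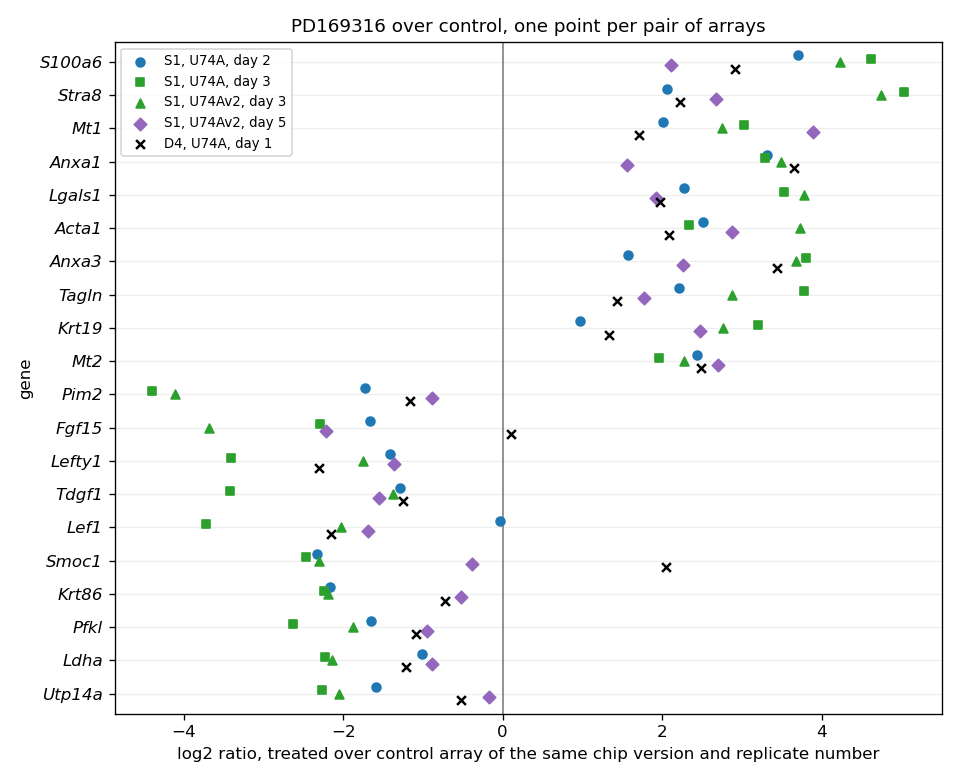
PD169316 against control for the genes with the largest changes in S1. Each point is the log2 ratio of a treated over a control array of the same chip version and replicate number (x axis), one line per gene, for 4 S1 pairs and the D4 pair (crosses), marked by hybridization day; S100a6 lies between 2.11 and 4.62 in the S1 pairs, and Lefty1 between -3.41 and -1.36.

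Single chip versions gave fewer calls. On U74Av2, 9 of 7050 probe sets passed (7 higher, 2 lower), and the named ones were Mt1, Mt2, Gadd45b, Tagln, Ephx2 and S100a6, which rose, and Lef1, which fell. The count ranged from 0 without PD169316 replicate 1 to 42 without PD169316 replicate 2, was 3 and 2 without control replicate 1 and 2, 2 and 4 without SB203580 replicate 1 and 2, and was 53 with the replicate block. On U74A, only S100a6 passed among 5681. That count was 3 and 10 without control replicate 1 and 2, 0 without either PD169316 array, and 9 with the block. Fold changes on the chip versions correlated across 5369 probe sets at r = 0.355, which are not independent replicates and include the shared RNA of day 3.

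Among the lists, actin cytoskeleton and SRF targets had the most changes, with 13 of 29 tested genes higher and 1 lower (18 and 1 adjusted over the list alone). Of these, only Acta1, Anxa3, Actn1, S100a6, Tagln, Tmsb4x and Lgals1 passed when the correlation of the z scores was allowed for. Camera at the preset correlation gave an adjusted p of 1.87e-19 on U74Av2 and 1.14e-11 on U74A, which did not hold (adjusted p = 0.231 and 0.654 with an estimated correlation). The lower call was for a probe set of Actb (-1.35 ± 0.30, adjusted p = 0.0317), whose ratio was negative in 3 of 4 pairs and which was at -0.91 without the day 3 controls (adjusted p = 0.596). This call rests on 1 probe set, and the separate Actb 3' control probe set had a higher signal with PD169316 in 4 of 4 S1 pairs (11715.3 against 7143.6 in the day 3 pair of U74A) and in D4. Primitive and visceral endoderm genes were higher in 6 of 19 (11 higher and 1 lower adjusted over the list alone): Krt8 (1.95), Col4a1 (1.71), Sparc (1.63), Krt18 (1.31), Serpinh1 (1.15) and Col4a2. None of these 6 genes passed when the correlation of the z scores was allowed for. Gata4 and Gata6 of this list, named in advance, were not called. In the S1 pairs (U74A replicate 1 and 2, then U74Av2), Gata4 had log2 ratios of 3.44, -0.31, -1.87 and -0.17. Those of Gata6 were -0.38, -0.92, -1.80 and 0.23, and it lay under the signal filter of the line fit on U74A. By camera the endoderm list passed on U74Av2 (adjusted p = 7.62e-07) and on U74A (adjusted p = 0.00018), but not with an estimated correlation (adjusted p = 0.231 and 0.669). The imprinted list had 2 of 16 genes higher, Igf2 (1.63) and Sgce, also adjusted over the list alone, and passed on both versions (adjusted p = 0.00377 and 0.00336), but not with an estimated correlation (adjusted p = 0.231 and 0.592).

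Pluripotency genes went both ways. Of 23 tested genes, Tdgf1, Fgf4 (-1.08), Phc1 (-0.98) and Utf1 (-0.90) fell and Tfcp2l1 (1.34) rose; adjusted over the list alone, 7 were lower and 2 higher, and camera did not pass (adjusted p = 0.0705 on U74Av2). Tfcp2l1 has a further tested probe set with the opposite sign. Pou5f1 did not pass over all genes (-0.57 ± 0.20, adjusted p = 0.223), and Nanog, tested on U74Av2 alone, had a log2 fold change of -0.19 with a 95% confidence interval from -0.73 to 0.35. In LIF and STAT3 targets, Pim1 (-1.09) and Mycn (-1.43) fell and Tfcp2l1 rose among 16 (3 lower and 2 higher adjusted over the list alone). On U74Av2, 11 genes of that list were higher and 6 lower, and camera did not pass (adjusted p = 0.974). The TGF-beta, Nodal and BMP list split. Id2 (1.72), Id1 (1.33), Tgfbi and Ccn1 rose and Lefty1, Tdgf1 and Nodal fell among 20, with 6 higher and 3 lower adjusted over the list alone.

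Genes of hypoxia and glycolysis were lower in 3 of 19, namely Pfkl, Pkm (-1.04) and Ldha (5 adjusted over the list alone), and the list passed on both versions (adjusted p = 0.000183 and 0.000158), but not with an estimated correlation (adjusted p = 0.617 and 0.684). MYC and ribosome biogenesis genes were lower in 3 of 19, namely Mycn, Srm (-1.13) and Ldha (3 adjusted over the list alone). That list had an adjusted p of 2.45e-06 on U74Av2 and 0.000644 on U74A, and an adjusted p of 0.424 and 0.669 with an estimated correlation. The cell cycle list had 0 calls of 40 genes by limma, also adjusted over the list alone, with 30 genes lower, and passed camera on U74A (adjusted p = 0.000266; adjusted p = 0.592 with an estimated correlation). The p38 pathway and immediate early list had 1 of 26 higher, Jund (0.80), 3 adjusted over the list alone, and passed camera on U74Av2 (adjusted p = 0.00377; adjusted p = 0.231 with an estimated correlation). Mapk14, which encodes p38 alpha, did not change detectably (0.19 ± 0.24, adjusted p = 0.832), nor did Mapkapk2 (0.26, adjusted p = 0.733), and Hspb1 lay under the signal filter. No list passed fry.

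Pro-apoptotic and p53 genes were higher in 3 of 23, namely Perp (1.57), Sfn (1.27) and Gadd45a (1.06), and 5 adjusted over the list alone. Among 15 anti-apoptotic genes Clu rose (1.16), also adjusted over the list alone, and Bcl2 did not pass (-0.40, adjusted p = 0.785). Bax had no probe set with its symbol alone. The metallothionein and oxidative stress list held 2 higher of 22, Mt1 and Mt2, both also adjusted over the list alone, and passed camera on U74A (adjusted p = 0.00336; adjusted p = 0.592 with an estimated correlation). In epiblast, ectoderm and neural genes, Crabp2 (1.69), Gap43 (1.59) and Nes (1.37) rose among 14 (4 higher and 3 lower adjusted over the list alone). Fgf5, named in advance, was not called. Its log2 ratios in the S1 pairs were -1.07 and 0.78 on U74A and -0.17 and -0.89 on U74Av2. Tfap2c (1.42) rose among 9 trophoblast genes, also adjusted over the list alone, and Cd9 (1.52) and Cd24a (1.18) among 23 of extracellular matrix and adhesion (3 adjusted over the list alone).

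In heat shock and chaperones, Serpinh1 rose among 17 genes (2 adjusted over the list alone), and among 10 housekeeping genes the Actb probe set fell, also adjusted over the list alone, while the Actb 3' control probe set was higher. By limma, 0 genes passed in primitive streak, mesoderm and muscle (of 12), endoplasmic reticulum stress and amino acid response (of 25), CDK inhibitors (of 6), cholesterol and fatty acid synthesis (of 15), fibroblast of feeder type (of 7) and endothelial and blood (of 10), and adjusted over the list alone also 0. In interferon and inflammation 0 of 8 passed over all genes, and B2m was higher and Ly6e lower adjusted over the list alone. In xenobiotic and AhR 0 of 2 passed, and Tiparp was lower adjusted over the list alone.

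SB203580 against control in S1 asked whether a second inhibitor of the same kinases gives the same changes. The genes with the smallest p that were lower with SB203580 were Dmtn and 2 genes of Nodal signalling, Lefty1 and Nodal, and none passed over all genes. Limma called 0 probe sets over both chip versions (249 at an unadjusted p under 0.05, where 268 would be met by chance), and also 0 on U74Av2 (335) and 0 on U74A (85). Allowing for the correlation of the z scores also gave 0. A control array moved the combined count to 1 when left out (U74Av2 control replicate 2), as did U74A PD169316 replicate 1, while PD169316 replicate 2 moved it to 2. With a block that set the day 3 arrays apart from all others, which equals the replicate number on U74Av2, 3 probe sets passed, all lower: Actb (-1.53, adjusted p = 0.0478, while its 3' control probe set was higher in 3 of 3 pairs), Lefty1 (-1.60, adjusted p = 0.0331) and Dmtn (-2.57, adjusted p = 0.00746).

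Without the block, Dmtn had a log2 fold change of -2.29 ± 0.46 (adjusted p = 0.0676; U74Av2 signal 54.2 ± 3.32 against 236 ± 28.1) and Lefty1 one of -1.91 ± 0.43 (adjusted p = 0.0676; 308 ± 71.6 against 1103 ± 96.4). Nodal was at -1.37 ± 0.27 (adjusted p = 0.108), Actb at -1.54 (0.165) and Cox6b2 at -1.48 (0.256). Each of these 5 genes was lower in 3 of 3 pairs. The smallest p among higher values belonged to Nnat (1.39, adjusted p = 0.279), Tagln (1.43, adjusted p = 0.365), and Rac1 (0.84), Nras (0.86) and Plk4 (0.93). Nanog, tested on U74Av2 alone, had a signal of 981 ± 67.3 against 2651 ± 335 (-1.43 ± 0.25, 95% confidence interval -1.97 to -0.89, lower in both pairs), with an adjusted p of 0.374. Mt1 (0.56), Mt2 (0.27) and S100a6 (0.59) did not pass (adjusted p = 0.995 each).

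Adjusted over the list alone, 3 of 20 genes of the TGF-beta, Nodal and BMP list were lower with SB203580 (Lefty1, Tdgf1, Nodal) and Id2 was higher. Calls of that kind were also made for Mest and Nnat (imprinted, higher), Tagln and Tmsb4x (actin, higher), Actb (actin and housekeeping, lower), Nnat and Zic2 (epiblast, higher and lower), Plk4 (cell cycle, higher) and Cd24a (extracellular matrix, higher), against 0 over all genes in every list. Camera passed for actin (higher, adjusted p = 1.4e-06), imprinted (higher, 0.0112) and pluripotency (lower, 4.34e-06) on U74Av2, and for hypoxia and glycolysis on U74A (lower, 0.0345). None of the 4 passed with fry or with an estimated correlation (adjusted p = 0.554, 0.505, 0.265 and 0.933 with an estimated correlation, in that order). With the replicate block the endoderm list also passed on U74Av2 (higher, adjusted p = 0.0406, and 0.0577 without it).

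The direct comparison of the inhibitors in S1, both at 10 µM, tested where their effects differed. Genes higher with PD169316 than with SB203580 included Mt1, Mt2, Acta1, Anxa1, Anxa3, Ephx2, Cpt1a and Igf2, and Pim2, Lef1 and Srm were lower. Of 5369 probe sets, 37 passed over both chip versions, 28 higher and 9 lower with PD169316 (31 genes; 576 at an unadjusted p under 0.05). Allowing for the correlation of the z scores left 6, which were Mt2, S100a6, Mt1, Ephx2, Cpt1a and 1 without a gene name, and a block that set the day 3 arrays apart from all others gave 88. The count was 72 and 76 without U74A control replicate 1 and 2, 15 without PD169316 replicate 1 of U74A, 12 and 111 without PD169316 replicate 1 and 2 of U74Av2, 17 without either U74Av2 SB203580 array, and 59 without the day 3 controls.

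S100a6 differed by 3.08 ± 0.36 (adjusted p = 0.000115; 95% confidence interval on U74Av2 from 1.86 to 4.11) and Mt1 by 2.36 ± 0.28 (adjusted p = 0.000115; 1.56 to 2.97). Mt2 differed by 2.08 (adjusted p = 0.000115; 1.59 to 2.97), Ephx2 by 2.49 ± 0.36 (adjusted p = 0.000716; 1.83 to 3.48) and Igf2 by 2.10 (adjusted p = 0.00133; 1.47 to 3.33). Also higher with PD169316 were Anxa1 (2.72), Acta1 (2.52), Ddit3 (2.35), Cpt1a (2.31), Lgals1 (2.29) and Fabp3 (2.20). Pim2 had the largest fall (-2.97 ± 0.48, adjusted p = 0.00472; -3.98 to -1.16), followed by Lef1 (-2.05), Utp14a (-1.57), Dnmt3a (-1.44), Srm (-1.38), Sfxn1 (-1.23) and Utf1 (-1.03). Allowing for the correlation of the z scores, none of these falls passed.

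Lefty1, Nodal and Tdgf1, which fell with PD169316, were not found to differ between inhibitors. The difference was -0.07 ± 0.43 for Lefty1 (adjusted p = 0.945; U74Av2 interval -0.40 to 1.003), 0.31 for Nodal (adjusted p = 0.795; -0.72 to 0.62) and -0.70 for Tdgf1 (adjusted p = 0.682; -1.03 to 0.52). Dmtn was higher with PD169316 than with SB203580 (1.84, adjusted p = 0.0365). For Nanog the difference on U74Av2 was 1.24 (95% confidence interval 0.70 to 1.77, adjusted p = 0.176). On U74Av2 alone Mt2 (2.28), Ephx2 (2.66) and Mt1 (2.27) passed (adjusted p = 0.0443 each; 22 probe sets with the replicate block). That count was 0 without PD169316 replicate 1 or either SB203580 array and 24 without PD169316 replicate 2. On U74A limma called 0 (213 at an unadjusted p under 0.05), 4 without control replicate 1 and 3 without control replicate 2.

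**Figure D2:**
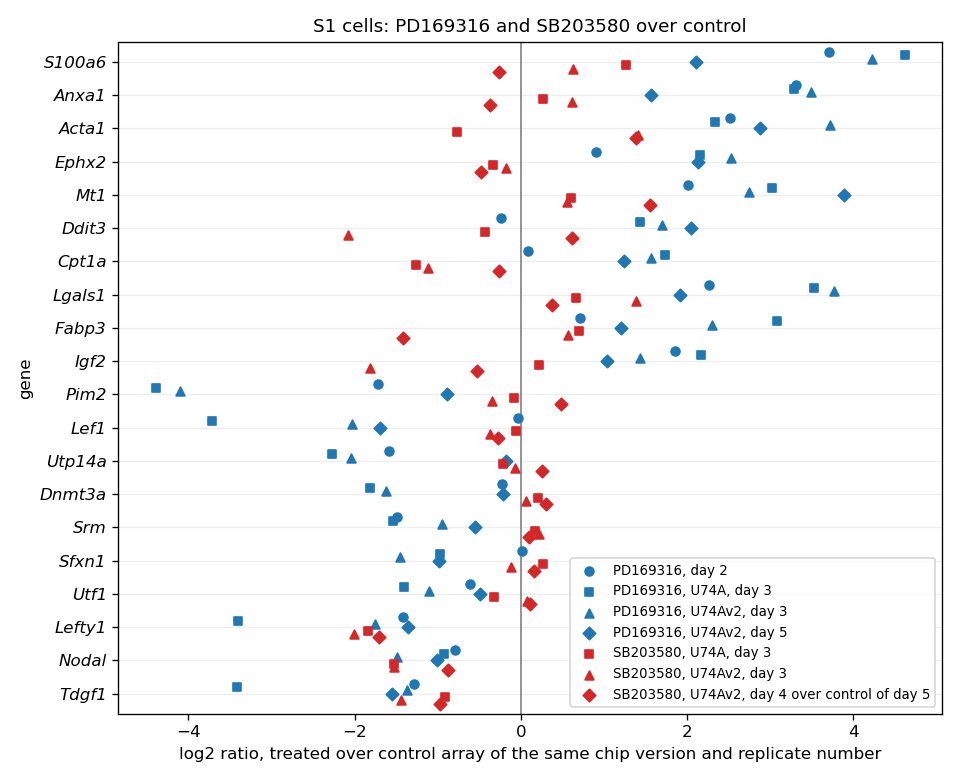
Both inhibitors in S1. Each point is the log2 ratio of a treated over a control array of the same chip version and replicate number (x axis), one line per gene, for PD169316 (blue) or SB203580 (red), marked by hybridization day; Mt1 lies between 2.02 and 3.90 with PD169316 and between 0.56 and 1.55 with SB203580, and Lefty1 is negative in every pair.

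Fold changes of the inhibitors, each against the controls of a different chip version, correlated across 5369 probe sets at r = 0.0525 and 0.0232. Those controls are not fully separate, since the day 3 controls appear to carry the same RNA on both versions. SB203580 fold changes on U74Av2 and U74A correlated with each other at only r = 0.145, against 0.355 for PD169316. Values near 0 therefore do not show that the effects of the inhibitors are unrelated. Within a version they correlated at r = 0.491 on U74Av2 and 0.313 on U74A, where simulated groups without any change gave 0.502 and 0.408 because they share their controls.

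By list, 5 of 29 actin genes (16 adjusted over the list alone), 2 of 22 metallothionein and oxidative stress genes (3) and 1 endoderm gene, Sparc (8), were higher with PD169316 than with SB203580. Of the pluripotency genes, 2 were higher and 1 lower (6 and 3 adjusted over the list alone), and of the MYC genes Srm was lower (5). On U74Av2 camera passed for actin (adjusted p = 1.42e-08), endoderm (0.000596), p38 pathway (0.0183), metallothionein (0.034) and TGF-beta genes (0.034), which were higher, and for MYC (4.32e-07), hypoxia and glycolysis (0.00319) and cell cycle genes (0.0183), which were lower. With an estimated correlation, the adjusted p was 0.546 for actin, endoderm and p38 pathway genes and 0.58 for the others. On U74A actin (6.85e-08), endoderm (0.00031) and metallothionein (0.0109) were higher and MYC (7.1e-07) and cell cycle (0.000578) lower. None of these 5 lists passed with fry or with an estimated correlation (adjusted p = 0.679 each with an estimated correlation).

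PD169316 was also given to D4, the feeder-dependent line, which asked whether the changes extend beyond S1. A fit of U74A with a term for the line called 12 of 6219 probe sets, all higher: S100a6 (3.75 ± 0.35, adjusted p = 0.000404), Mt2 (2.30, adjusted p = 0.000404), Lgals1 (2.59), Tmsb4x (2.51), Mt1 (2.25), Tagln (2.47), Anxa1 (3.42), Anxa3 (2.94), Acta1 (2.31), Igf2 (1.73), Actn1 (1.29) and 1 without a gene name. Each was higher in the D4 pair and in both U74A pairs of S1, which are the arrays of the fit itself. The count was 1 without the D4 control, 3 without D4 PD169316, 31 without S1 control replicate 2, 1 and 7 without S1 PD169316 replicate 1 and 2, and 19 with the hybridization day as a block.

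In D4, 89 of the 101 probe sets called in S1 had the same sign (88.1%), against 2961 of 5224 that were tested and not called (56.7%). Across 6219 probe sets, D4 and S1 fold changes on U74A correlated at r = 0.143, and probe sets are not independent replicates. With 1 array each, D4 values carry no error. The largest log2 ratios were higher for Anxa1 (3.65, signal 12.4 to 402), Anxa3 (3.44), Ddit3 (3.21), Laptm5 and Miip (3.11), and lower for Eomes (-3.58, signal 382 to 13.4), Sez6l (-3.46), Car12 (-3.41), Sgpp1 (-3.40) and Homer3. For Anxa1, Miip and all 5 lower genes the smaller signal lay under the floor of 32, so their ratios and their rank depend on it. Lefty1 was at -2.31 in D4 and Mt1 at 1.72. The test of a difference in effect between lines called 0 by limma (149 at an unadjusted p under 0.05), with the smallest p for Smoc1, at -1.87 in S1 over both versions and 2.05 in D4.

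Untreated and treated D4 compared with S1 on U74A asked how the lines differ. Interferon and actin genes leaned higher in D4 and pluripotency genes lower, while no single gene passed. Limma called 0 of 6219 probe sets (392 at an unadjusted p under 0.05, smallest adjusted p = 0.399); the smallest p belonged to Inpp5d (-2.40), Chchd10 (-1.21), Trap1a (-1.57), Sprr2e (-1.66) and Mms19 (-1.99). All 12 tested genes of the interferon list were higher in D4 (median log2 difference 0.85, camera adjusted p = 2.45e-05), as were 24 of 30 actin genes (0.558, adjusted p = 3.37e-06). Neither passed with fry or with an estimated correlation (adjusted p = 0.681 each with an estimated correlation). Of 15 cholesterol genes, 12 were higher (0.415, adjusted p = 0.0146; adjusted p = 0.714 with an estimated correlation), and of 25 pluripotency genes, 20 were lower (-0.432, adjusted p = 0.000825; adjusted p = 0.681 with an estimated correlation). Fibroblast genes of feeder type did not pass (9 of 12 higher, adjusted p = 0.201), nor did xenobiotic genes (adjusted p = 0.871). The D4 arrays were hybridized on a day of their own, so line and day cannot be told apart.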

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

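Alternatives chosen only after the data were seen are the z scores combined allowing for their correlation, 1 log2 ratio per hybridization day, a block that sets the day 3 arrays apart from all others, blocks by hybridization day, and leaving out the day 3 arrays or controls. The others were set beforehand. No called list turned its direction under the alternatives run, nor did any named gene called in the combined tests, where it was still tested. Other called genes were not checked for this. Some lists without a call did, such as LIF and STAT3 targets and epiblast genes for PD169316 on U74Av2, which leaned higher without and lower with the replicate block. Of the named genes, 2309 values kept their side of the threshold under the alternatives set beforehand, 293 lost a call and 37 gained one. Under those added the numbers were 452, 232 and 5. Direction was compared only for genes with a call, so values that stayed without a call may have changed sign. Of the counts and correlations, 123 values of the alternatives set beforehand lay within 1.5 times or within the spread and 94 did not, against 5 and 11 for those added. The list results kept their call in 113 values and lost it in 81. Signal over background limits dim genes, since 21.8% to 29.9% of an array lay at or under the floor. Where no reason is given, the cause was not tested. Where an alternative moved a count to 0 by limma, 170 to 782 probe sets had an unadjusted p under 0.05. The numbered block of D4 against S1 was not run, because D4 titles carry no number.

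For PD169316 against control over both chip versions (101), the count was 102 with quantile normalization, 94 with a minimum signal of 200, 99 with a floor of 1 and 70 with a floor of 100. It was 1 without a filter and 31 without the intensity trend. On U74Av2 (9) the count was 5 with quantile normalization, 3 without a filter, 5 with a floor of 1, 1 with a floor of 100, 0 without the trend and 4 with only the 2 groups compared. On U74A (1) it was 2 with quantile normalization, 0 without a filter, 6 with a minimum signal of 200, 0 with a floor of 100 and 0 without the trend.

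The block on replicate number, which pairs arrays of a shared hybridization day, gave 199 for PD169316 over both versions, 53 on U74Av2 and 9 on U74A (the U74A SB203580 array was left out of these fits, which without the block gave 104 over both versions and 1 on U74A), and 22 for PD169316 against SB203580 on U74Av2. Of the blocks added later, the one that sets the day 3 arrays apart from all others gave 3 for SB203580 and 88 for PD169316 against SB203580 over both versions, and the one by hybridization day gave 19 for PD169316 with a line term.

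Among the other added alternatives, allowing for the correlation of the z scores gave 12 for PD169316 over both versions and 6 for PD169316 against SB203580. A limma test of 1 log2 ratio per day gave 0 for PD169316 over the 3 S1 days, 0 with the D4 day added and 0 without day 3 (267, 458 and 184 at an unadjusted p under 0.05). On simulated data that test made 51 calls and recovered 47% of changes of log2 2 and 3% of changes of log2 1. Without the day 3 controls the counts were 30 for PD169316 and 59 for PD169316 against SB203580 over both versions. Without the day 3 arrays the line term gave 6, from fewer arrays.

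Without a filter SB203580 had 3 calls on U74Av2, 74 on U74A and 2 over both versions, and the difference of effects between lines had 403. Of the 403, 314 lay at the floor on all S1 control and PD169316 arrays, as did 64 of the 74, so values set to the floor account for most of them. PD169316 against SB203580 had 0 on U74Av2, 73 on U74A (64 of them at the floor) and 3 over both versions without a filter, and the line term had 0.

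For PD169316 against SB203580 on U74Av2 (3), quantile normalization, a minimum signal of 200, a floor of 100 and no trend each gave 0. Over both versions (37), a floor of 100 gave 16 and no trend 17. With the line term (12), a floor of 100 gave 6 and no trend 0. The correlation of PD169316 effects in D4 and S1 (0.143) was 0.153 with quantile normalization, 0.11 without a filter, 0.236 with a minimum signal of 200, 0.132 with a floor of 1, 0.226 with a floor of 100 and 0.16 by rank. The correlations of PD169316 with SB203580 effects across chip versions (0.0525 and 0.0232) moved by less than their spread. That spread was the SD of r between single pairs of arrays (0.0495 and 0.0803). The first ranged from 0.0483 without a filter to 0.0639 with a floor of 100. The second ranged from 0.00693 without a filter to 0.102 with a minimum signal of 200. D4 against S1 gave 0 under every alternative.

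Leaving out single arrays gave 24 to 164 for PD169316 over both versions, 0 to 42 on U74Av2 and 0 to 10 on U74A. It gave 0 to 2 for SB203580 over both versions, 12 to 111 for PD169316 against SB203580 over both versions, 0 to 24 on U74Av2 and 0 to 4 on U74A, and 1 to 31 with the line term. Where this left 1 array in a group, that array was assumed to vary like the other groups.

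Among the gene lists, both an estimated correlation and fry gave 0 in every comparison. The preset correlation gave 6 for PD169316 on U74Av2 and 7 on U74A, 3 and 1 for SB203580, 8 and 5 for PD169316 against SB203580, and 4 for D4 against S1. Without a filter the lists of PD169316 against SB203580 were 4 on U74Av2 and 3 on U74A, and those of SB203580 on U74A were 0. With quantile normalization the latter were 2. The replicate block added the endoderm list for SB203580 on U74Av2 (4 lists).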

Other observations

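The tests of explanations given here were chosen only after the result was seen: other splits of the arrays, ratios on separate hybridization days, counts with fewer arrays, and the other genes of the pluripotency list. The genes of the next paragraph were picked after their values were seen and stand for no fixed list.

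Further genes rose with PD169316 in S1 over both chip versions. Ephx2, which encodes soluble epoxide hydrolase, rose by 1.93 ± 0.32 on the log2 scale (SE; adjusted p = 0.00202), Plin2, a lipid droplet coat protein, by 1.86 ± 0.38 (adjusted p = 0.00887), Fabp3, a fatty acid binding protein, by 1.83 ± 0.41 (adjusted p = 0.0194), and Cpt1a, which admits fatty acids to mitochondria, by 1.16 ± 0.30 (adjusted p = 0.0479). Ephx2, Fabp3 and Cpt1a were higher in 4 of 4 S1 pairs, while in D4 Ephx2 (-0.10) and Cpt1a (-0.17) were not. Capn2 (2.07), Anxa2 (2.05) and Klf6 (1.45) rose as well (adjusted p = 0.00232, 0.0207 and 0.0158). Mkrn1 (-1.33), Ptk7 (-1.45) and Upp1 (-1.45) fell (adjusted p = 0.00376, 0.0158 and 0.0323). None of these 10 genes passed when the correlation of the z scores was allowed for (adjusted p = 0.0524 for Ephx2 and Capn2).

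The first pattern is the set of 101 calls for PD169316 in S1 over both chip versions. The 18 splits of the control and PD169316 arrays are too few for a share under 0.05; the real split gave 101, the highest other 3, and 1 split, the real one, gave as many. With a line term on U74A the 10 splits are also too few; the real split gave 12, the highest other 1, and again 1 split gave as many. The tables argue against the shared RNA of day 3 as the whole source. Of the 100 probe sets with the smallest p on U74Av2, 80% kept their sign on day 1 and 76% on day 2. The RNA of these days is on U74A alone. Both values lay above the central 95% range of random sets (upper bounds 64% and 63%). Those 100 were picked on U74Av2 alone and are not the set of 101 calls, and the random sets were not matched on signal. Probe sets that change together also make such a range too narrow. The tables also argue against the quality of the day 3 control RNA as the whole source. The 100 probe sets with the largest day 3 ratios had median signed log2 ratios of 0.732, 0.693 and 0.861 on days 1, 2 and 5. These lay above the central 95% range of random sets matched on mean signal (upper bounds 0.2, 0.236 and 0.181). The medians are below the 2.29 of day 3, so a part of the day 3 ratios may still come from that RNA quality.

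The second pattern is that SB203580 gave no call where PD169316 gave 101, a contrast that is smaller under other settings. With the correlation of the z scores allowed for, PD169316 had 12 calls and SB203580 0, and a block that set the day 3 arrays apart gave SB203580 3. Whether fewer SB203580 arrays account for the contrast cannot be told. With only 1 of its U74A arrays, PD169316 still gave calls in the combined test, but that test treats the chip versions as independent. The smaller design was not run with the correlation of the z scores allowed for. The U74Av2 SB203580 array of replicate 2, hybridized on a day of its own, cannot be told apart as a cause: with the treated arrays of day 3 alone, against all controls, SB203580 had 0 calls and PD169316 165, but these treated arrays appear to carry 1 RNA per treatment on both versions. The inhibitors differed directly in 37 probe sets (6 with the correlation allowed for), and no biological explanation was tested.

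The third pattern is the lower Lefty1, Nodal and Tdgf1, called with PD169316 and below 0 without passing for SB203580, where Lefty1 alone passed with a block that set the day 3 arrays apart (-1.60, adjusted p = 0.0331). Chance values of the shared controls cannot be told apart from an effect of PD169316: the D4 pair, which did not enter the choice of these genes, had a mean log2 ratio of -1.6 over the 3 genes (lower bound of the central 95% range of random triples -0.932), but it is a single pair. They also cannot be told apart from an effect of SB203580, because every S1 control entered that choice; ratios of SB203580 arrays to controls of another day had means between -1.7 and -1.19. For PD169316, the 26 other pluripotency genes on U74Av2, Nanog among them, had a median log2 fold change of -0.0769 (SD 0.687, range -1.7 to 1.12). The least lowered of the 3 genes was at -1.25. A fall shared by the whole list was thus not seen. The 3 genes were picked for their low values on these arrays, so the gap was partly given by the choice. A lower share of undifferentiated cells therefore stays open as a cause. With SB203580 this cause stays open as well. The 26 genes had a median of -0.483 (SD 0.509, least lowered of the 3 genes -1.2), and Nanog was at -1.43. The list was lower by camera on U74Av2 (adjusted p = 4.34e-06, and 0.265 with an estimated correlation).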
